A study of Mus musculus with 20 samples.

How the data were processed

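RNA of gastrocnemius and triceps from female C57BL/6 mice was measured on 20 arrays. Per the labels' protocols, total RNA was extracted with Trizol, purified on RNeasy columns and checked on a BioAnalyzer, and biotinylated cRNA was prepared from 4 ug of total RNA. The deposited table holds 10748 probe sets on a log2 scale, per the values, which run from -3.66 to 13.3. Signals were computed with MAS5, per the submitters' processing notes; its version, target level and any filter are not given in the sources used here. Array medians lie between 6.61 and 6.76 and trimmed means of the linear signal between 229 and 240, so the deposited log2 values were used without further scaling. MAS5 signals have no floor, no detection calls were used here, and a fold change against a group with a mean near the lower end of the scale is therefore uncertain. Control probe sets for RNA quality were not analysed here.

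Samples were grouped by the titles into SOD1G93A (called SOD1) and non-transgenic (NTg) gastrocnemius and triceps and crushed gastrocnemius, 4 arrays each. Per the labels, the sciatic nerve was crushed at 12 weeks for 30 s and muscles were taken at 14 weeks. The genotype of the crushed mice is not given in the sources used here, and no group with a sham operation was analysed. The design text gives 4 SOD1 and 4 NTg mice for both muscles, but no label ties a replicate number to a mouse. The replicate numbers were not taken as pairs.

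Probe sets in the lowest 30% by mean over all arrays (under a log2 mean of 5.88) were left out, which left 7523. Gene symbols came from the platform annotation: 9874 probe sets had 1 symbol, 387 several and 487 none, and 9862 of the single-symbol probe sets matched the mouse RefSeq gene table (GRCm38.p6) by gene ID. A gene was represented by its single-symbol probe set with the highest mean, which gave 4832 genes. A model with 5 group means was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend), leaving 15 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets within each of 6 comparisons: SOD1 against NTg in each muscle, crush against NTg, SOD1 against crush, the SOD1 effect in gastrocnemius minus triceps, and gastrocnemius against triceps in NTg mice. An adjusted p under 0.05 was called. Figures were drawn with matplotlib 3.10.9.

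Gene lists, 32 in number, were fixed before the data were examined: neuromuscular junction and muscle excitability, myogenic regulators and developmental sarcomere, atrophy ubiquitin ligases and FoxO genes, proteasome subunits, autophagy and lysosome, slow-fibre and fast-fibre sarcomere, glycolysis and glycogen, mitochondrial respiratory chain, TCA cycle and fatty-acid oxidation, calcium handling and excitation-contraction coupling, extracellular matrix and fibrosis, antioxidant and metal response, unfolded protein and integrated stress response, heat shock and small chaperones, polyamine and p53-target genes, immediate-early genes, interferon response, complement and antigen presentation, circadian clock, cytosolic ribosomal proteins, cell cycle, hindlimb and forelimb position genes, and markers of fibroblast and fibro-adipogenic cells, macrophages, lymphocytes and granulocytes, Schwann cells and nerve, endothelium, smooth muscle and pericytes, adipocytes, and blood and erythroid cells. They were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists with a tested member in each comparison, and the members were also adjusted over the list alone.

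Named genes followed a fixed rule. In each comparison against NTg these were the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap, and up to 4 called members of each list, or the 1 or 2 largest changes where no member was called; in the other comparisons the 5 largest rises and falls; and the mouse Sod1 probe set throughout. Symbols that name only a clone or a predicted gene were passed over. Genes of the fit without crush replicate 4 and genes below the filter were named after their values were seen.

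The alternatives were quantile normalization, subtraction of the 75th percentile, no filter and a filter at 60%, a fit on the compared arrays alone, the replicate number as a block, the mouse as a random block, array weights, a robust prior, no trend, an added 2-fold threshold, the mean of the probe sets of a gene, an estimated inter-gene correlation, and leaving out each array in turn. The fits without crush replicate 4 and without NTg triceps replicate 4 in the comparisons they do not belong to were chosen after seeing the data. For the overlap of the comparisons against shared NTg arrays, unchanged groups were simulated 100 times, with noise independent between probe sets. The controls were also split between the comparisons. For the overlap of both muscles, the covariance that shared mice would give with no change was computed from the deviations of the arrays from their group means, a reference chosen after seeing the data.

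The scripts were tested on simulated data of 7523 probe sets with 200 changed. For SOD1 against NTg gastrocnemius the fit recovered 23.9% of changes of 1.5-fold, 71.6% of 2-fold and 98.5% of 4-fold, with 3.01% of its calls false. The 2-fold recovery was 76.1% for SOD1 against NTg triceps, 80.6% for crush against NTg, 88.1% for SOD1 against crush, 56.7% for the difference between muscles and 83.6% for gastrocnemius against triceps, with 4%, 5.81%, 8.43%, 4.27% and 5.66% of calls false. Each 2-fold recovery rests on 67 changed probe sets. The simulated noise had the same spread in every group and no outlying array, so recoveries of comparisons of 2 groups differ only by the random draws.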

Results

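Gene expression was measured on 20 Affymetrix arrays, each hybridised with RNA of 1 muscle sample from female C57BL/6 mice aged 14 weeks. The arrays fall into 5 groups of 4: gastrocnemius (a hind limb calf muscle) and triceps (a fore limb muscle) of mice carrying a mutant human SOD1 transgene (SOD1G93A, called SOD1 here) at a symptomatic stage, a model of amyotrophic lateral sclerosis; the same muscles of non-transgenic (NTg) mice; and gastrocnemius of mice whose sciatic nerve had been crushed 2 weeks before, as a control for denervation. The titles call the replicates biological replicates, and the number of arrays, 4 per group, limits the precision of every value. Array medians lay between 6.61 and 6.76 on the log2 scale, and Pearson's r across probe sets within a group ranged from 0.917 to 0.973. The first principal component carried 33.6% of the variance and the second 22.5%. The group, filter and test choices were made before the data were examined. All fold changes below are differences of group means of log2 signal, with the standard error (SE) of the limma fit and n = 4 per group.

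**Figure D1:**
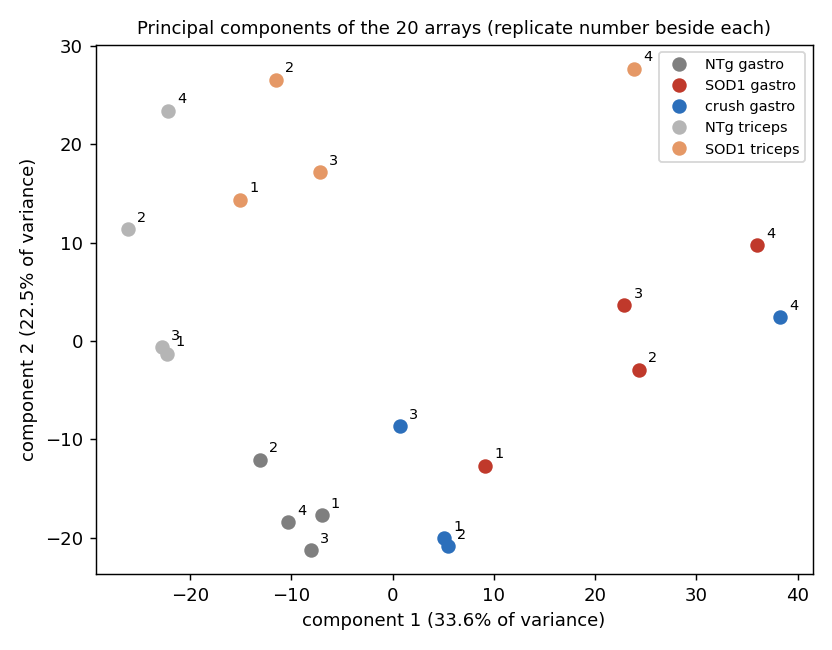
Principal components of the 20 arrays, with component 1 (33.6% of the variance) on the x axis and component 2 (22.5%) on the y axis; each point is an array, coloured by group, with its replicate number beside it. Replicate 4 of the crush group lies at 38.3 on component 1, and crush replicates 1 to 3 lie between 0.673 and 5.51. SOD1 gastrocnemius replicates 1 to 4 lie at 9.15, 24.4, 22.9 and 36.0.

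The first comparison asked how gastrocnemius of symptomatic SOD1 mice differed from that of NTg mice. Chrna1, the alpha subunit of the muscle acetylcholine receptor, was 11.6-fold higher (log2 change 3.54, SE 0.75, adjusted p = 0.00846), with a mean log2 signal of 9.99 ± 0.98 (SD, n = 4) in SOD1 and 6.45 ± 0.29 in NTg muscle. Myog, a transcription factor of muscle differentiation, was 9.47-fold higher, Cdkn1a, an inhibitor of cyclin-dependent kinases, 12.1-fold, Gadd45a, a growth arrest gene, 10.7-fold, and Ankrd1, an ankyrin repeat protein of the sarcomere, 14.8-fold. Sln, which encodes the calcium pump regulator sarcolipin, was 29.4-fold higher (95% interval 12.1 to 70.9). The largest rises were those of Tubb6, a beta tubulin (41.7-fold, log2 change 5.38, SE 0.63, adjusted p = 0.000154), Cpne2 (31-fold) and Krt18, a keratin (30.4-fold), whose NTg means were low (3.14, 3.71 and 4.54), so that these folds rest on dim signals. Without NTg replicate 3 the folds of Cpne2 and Krt18 were 18.2 and 16.1, and without NTg replicate 2 that of Sln was 19.3. Atp13a3 was 9.14-fold higher.

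Pla2g7, which inactivates platelet-activating factor, fell by 2.62 on the log2 scale (SE 0.43, adjusted p = 0.00331). Pfkfb3, which makes the chief activator of phosphofructokinase, fell by 2.54 (SE 0.54, adjusted p = 0.00876), from 9.79 ± 0.12 (SD, n = 4) in NTg to 7.25 ± 0.78 in SOD1 muscle. Chac1 fell by 2.06, Mylk2, the myosin light chain kinase of skeletal muscle, by 1.92, Tspan8 by 1.76, Fbp2, the muscle fructose bisphosphatase, by 1.74, Rasd2 by 1.73, Gpt2, an alanine aminotransferase, by 1.69, Smox, the spermine oxidase, by 1.62, and Cmbl by 1.47. The endogenous mouse Sod1 probe set had a log2 change of 0.40 (SE 0.19, adjusted p = 0.172).

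**Figure D2:**
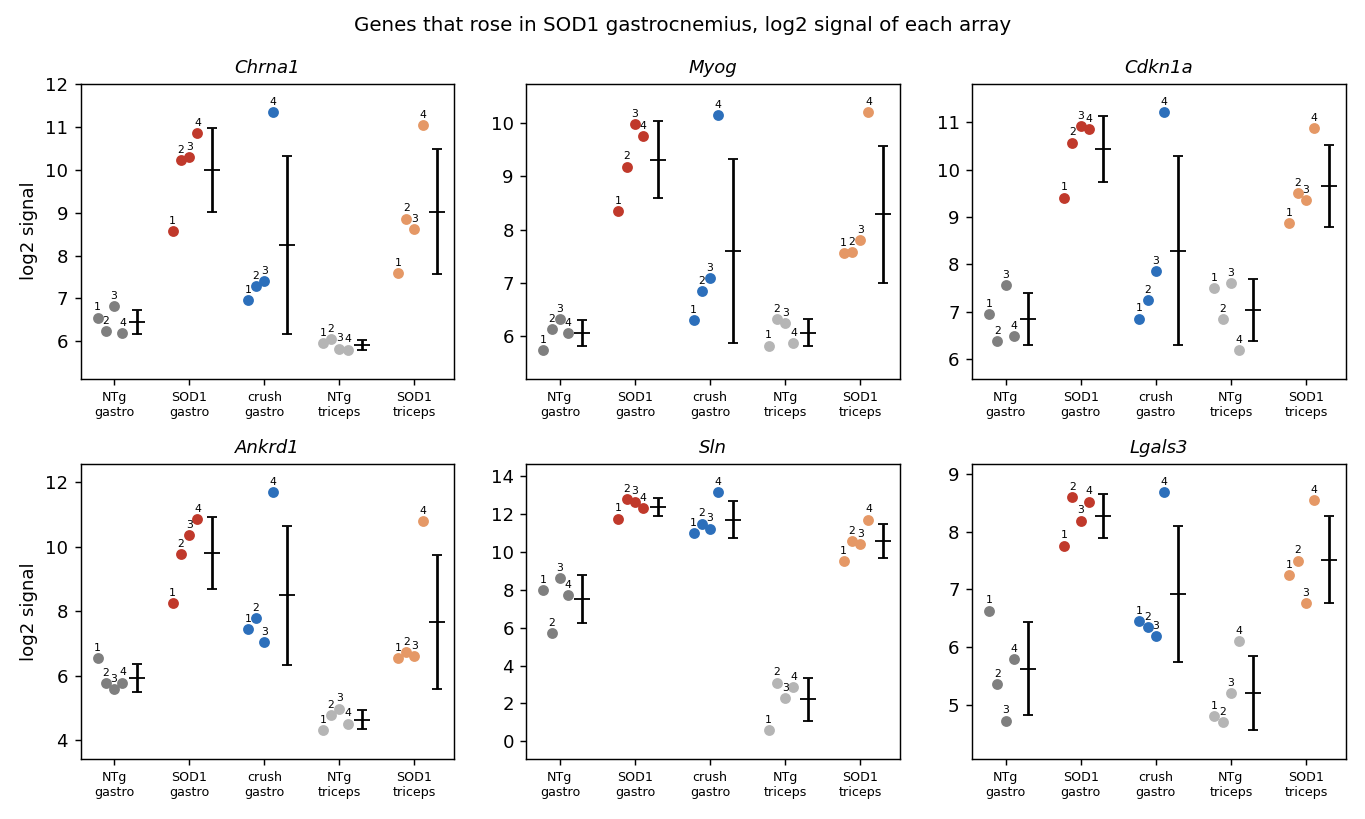
Log2 signal (y axis) of 6 genes that rose in SOD1 gastrocnemius, for each array of the 5 groups (x axis); points are arrays labelled with their replicate number, and bars are the group mean ± SD of 4 arrays. Chrna1 lies between 6.97 and 7.4 in crush replicates 1 to 3 and at 11.3 in crush replicate 4.

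The fixed gene lists gave the wider picture. Of 11 tested genes for myogenic regulators and developmental sarcomere, 7 rose and 0 fell (8 rose when adjusted over the list alone), and the median log2 change was 2.13 (camera, adjusted p = 0.000179, and 0.368 with a correlation estimated from the data). Of 9 genes of the neuromuscular junction and muscle excitability list, Chrna1, Chrnb1 (log2 change 1.75) and Utrn, the sarcolemmal protein utrophin (0.66), rose, and Clcn1, the muscle chloride channel, fell by 1.18. Adjusted over the list alone 4 rose and 1 fell, and the list itself did not pass (adjusted p = 0.107). Of 24 genes of glycolysis and glycogen, 9 fell and 0 rose (10 fell when adjusted over the list alone), and the list passed (adjusted p = 1.94e-06, and 0.445 with an estimated correlation). Among them were Phka1 and Phkg1, subunits of phosphorylase kinase, which fell by 1.39 and 1.42. Of 20 genes of calcium handling and excitation-contraction coupling, 4 fell (6 when adjusted over the list alone), and the list passed (adjusted p = 0.0213, and 0.445 with an estimated correlation). These were Jph1 and Jph2, which join the tubule and reticulum membranes, by 1.07 and 0.89, and the calcineurin subunits Ppp3cb and Ppp3ca by 0.93 and 0.50. Another probe set of Ppp3cb had a log2 change of 0.27. The 55 respiratory chain genes had a median of -0.15 with none past the threshold singly or adjusted over the list alone (list adjusted p = 0.0122, and 0.729 with an estimated correlation).

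Markers of macrophages moved in the same muscle. Of 11 tested markers, 8 rose (10 when adjusted over the list alone), and the list passed (adjusted p = 1.94e-06, and 0.368 with an estimated correlation). Among them were Lgals3, which encodes galectin-3 (6.24-fold), the complement genes C1qa (3.62-fold) and C1qb (1.90-fold), and the lysosomal protease Ctss (2.31-fold). Without NTg replicate 4, where C1qa was at 2.88, its log2 change went from 1.85 to 1.08 and its call was lost (adjusted p = 0.0505). Of 6 genes for complement and antigen presentation, 4 rose (5 when adjusted over the list alone; list adjusted p = 0.000381, and 0.368 with an estimated correlation). These were the class II genes H2-Aa (3.37-fold), H2-Eb1 (2.95-fold) and Cd74 (2.08-fold), and Serping1 (1.51-fold). Of 18 heat shock and small chaperone genes, 5 rose (8 when adjusted over the list alone; list adjusted p = 0.0213, and 0.368 with an estimated correlation), with Hspb8 at 2.73-fold and Hspa1b at 2.14-fold. The 31 proteasome subunits had a median of 0.28 and 2 rose, Psma5 and Psmd11 (1 when adjusted over the list alone; list adjusted p = 0.000213, and 0.596 with an estimated correlation). Another probe set of Psmd11 had a log2 change of -0.0013. The 31 genes of extracellular matrix and fibrosis had a median of 0.33 and none passed singly or adjusted over the list alone (list adjusted p = 0.00559, and 0.596 with an estimated correlation). The metallothioneins Mt2 (4.12-fold) and Mt1 (2.18-fold) rose among 5 rising genes of 23 in the antioxidant and metal response list (5 when adjusted over the list alone), which did not pass as a list (adjusted p = 0.151).

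Other lists did not pass as lists, and several of them held called members. Of 22 autophagy and lysosome genes, Map1lc3a, the autophagosome protein LC3, rose 2.51-fold, Ctsd and Lamp2 rose and Tfeb fell by 0.67 (3 rose and 2 fell when adjusted over the list alone; list adjusted p = 0.356). Foxo1 rose 1.65-fold among 11 genes of the atrophy ubiquitin ligase and FoxO list (1 when adjusted over the list alone; list adjusted p = 0.694). Of 14 polyamine and p53-target genes 6 rose and 2 fell (7 and 3 when adjusted over the list alone; list adjusted p = 0.0656), Odc1, the ornithine decarboxylase, rising 2.16-fold. The immediate-early genes Egr1, Jun and Ccn1 rose 2.47-, 2.31- and 2.30-fold, Egr1 just within the threshold (adjusted p = 0.04997). They made 3 of 12, and 4 when adjusted over the list alone (list adjusted p = 0.115). H2-K1 rose 1.91-fold in the interferon response list (1 of 5, and 1 when adjusted over the list alone; list adjusted p = 0.115). In the unfolded protein and integrated stress response list Canx rose and Chac1 fell (2 rose and 1 fell when adjusted over the list alone; list adjusted p = 0.277). In the list for the TCA cycle and fatty-acid oxidation Slc25a20 rose and Pdk2 fell (1 and 1 when adjusted over the list alone; list adjusted p = 0.33). Abcc9, a potassium channel subunit, fell by 0.60 in the smooth muscle and pericyte list (1 rose and 1 fell when adjusted over the list alone; list adjusted p = 0.898). Mylk2 fell in the fast-fibre sarcomere list (0 when adjusted over the list alone; list adjusted p = 0.885), whose median was 0.14 while its mean was -0.022 and the test pointed down. Hoxa10, the only tested hindlimb position gene, fell by 0.82 (1 when adjusted over the list alone; list adjusted p = 0.116). Hoxd8, the only tested forelimb position gene, had a log2 change of -0.57 (adjusted p = 0.0502), and the list did not pass (1 fell when adjusted over the list alone; adjusted p = 0.21). The remaining lists held 0 called genes over all probe sets and adjusted over the list alone. Their adjusted p was 0.356 for Schwann cells and nerve, 0.25 for adipocytes, 0.332 for endothelium, 0.212 for fibroblast and fibro-adipogenic cells and 0.363 for lymphocytes and granulocytes. It was 0.246 for slow-fibre sarcomere, 0.885 for circadian clock, 0.186 for cytosolic ribosomal proteins and 0.34 for cell cycle. The list for blood and erythroid cells had 0 tested members.

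In total, limma called 902 of 7523 probe sets for SOD1 against NTg gastrocnemius, 449 higher and 453 lower, in 692 named genes. At the unadjusted level, 2217 had an unadjusted p under 0.05 where 376 would by chance, and 1958 (26%) had groups that did not overlap, where chance gives 2.86%. Among the 10 largest rises only Ankrd1 lost its call on leaving out an array (SOD1 replicate 4, adjusted p = 0.0554), while 19 of 61 called genes named by rule or list kept theirs whichever array of the compared groups was left out. The count was 442, 419, 498 and 365 without NTg replicates 1 to 4, and 372, 417 and 178 without SOD1 replicates 2, 3 and 4. The matrix list lost its call without NTg replicate 4 (adjusted p = 0.0918) and the respiratory chain list without SOD1 replicate 4 (median -0.053, adjusted p = 0.295), while without SOD1 replicate 1 its median was -0.24. The camera tests used a preset inter-gene correlation of 0.01; with a correlation estimated from the data, 2 of 52 called lists over all comparisons held, both in the comparison of muscles in NTg mice. These calls moved with crush replicate 4, without which neither of the 2 held (adjusted p = 0.0512 for slow-fibre sarcomere and 0.0569 for Schwann cells and nerve) and endothelium and polyamine and p53 targets in triceps did (0.0305 each), in a fit chosen after seeing the data.

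**Figure D3:**
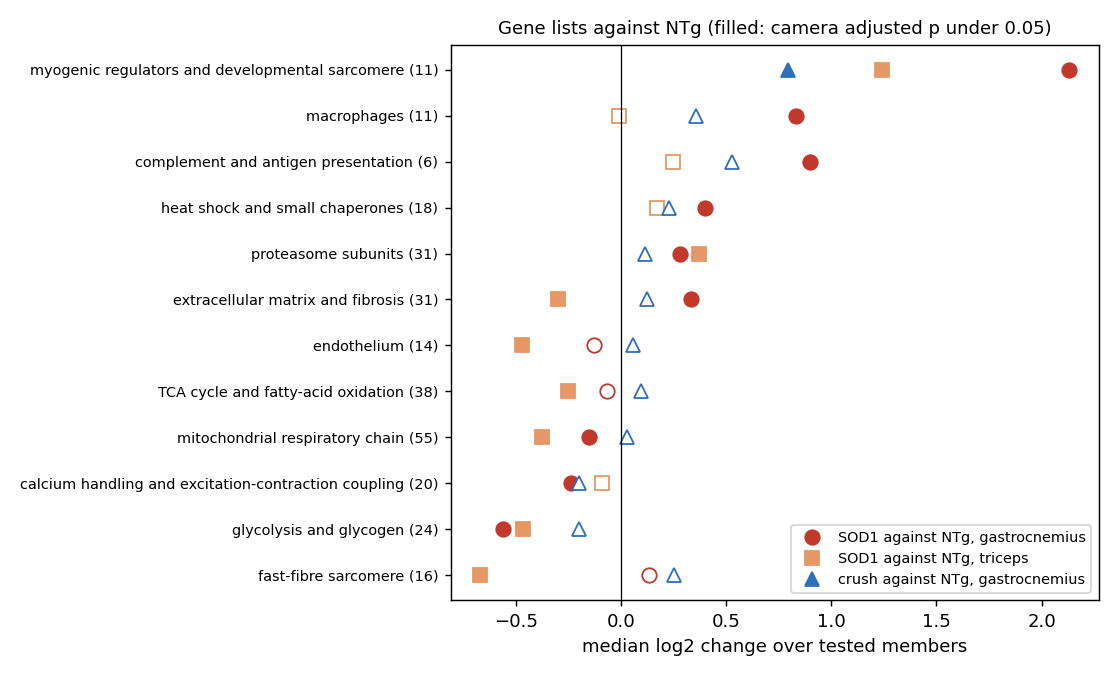
Median log2 change over the tested members (x axis) of 12 fixed gene lists (y axis, number of tested members in brackets) in 3 comparisons against NTg; each point is a list in a comparison, and filled points passed camera's adjusted p threshold of 0.05 with the preset correlation. The myogenic list has medians of 2.13, 1.24 and 0.80 in SOD1 gastrocnemius, SOD1 triceps and crushed gastrocnemius.

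The same contrast in triceps asked whether a fore limb muscle of SOD1 mice changed. Sln rose most, with a log2 change of 8.34 (SE 0.61, adjusted p = 1.06e-07), from 2.21 ± 1.14 (SD, n = 4) in NTg to 10.55 ± 0.90 in SOD1 triceps, a 325-fold difference with a 95% interval of 134 to 785 that rests on a dim NTg signal. Cpne2 (27.5-fold), Tubb6 (12.1-fold), Sh3d19 (4.96-fold) and Mt2 (3.59-fold) rose, as did Ampd3, an AMP deaminase (3.46-fold), Nabp1 (3.41-fold), Errfi1, an inhibitor of epidermal growth factor receptor signalling (3.22-fold), Jun (3.09-fold) and Nrip1 (2.43-fold). Nap1l1, Mob4, Nxn and Psme3ip1 rose by 0.94, 0.87, 0.82 and 0.72 on the log2 scale. Galnt7 (5.07-fold) and Odc1 (2.95-fold) completed the 16 genes called, each by a probe set other than the one with the highest mean over all arrays, which had log2 changes of 1.24 (adjusted p = 0.178) and 1.09 (adjusted p = 0.0955). These 6 genes were named after their values were seen. Lgals3 had a log2 change of 2.31 (adjusted p = 0.0571), Chrna1 of 3.11 (adjusted p = 0.0955), Ankrd1 of 3.03 (adjusted p = 0.155, and 1.99 without SOD1 replicate 4, at 10.80 where the next array was at 6.73), Cdkn1a of 2.62 (adjusted p = 0.107) and mouse Sod1 of 0.16 (adjusted p = 0.683).

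Gene lists moved in triceps although few of their members passed singly. The 55 respiratory chain genes had a median log2 change of -0.37 and 55 of them were lower (adjusted p = 4.58e-16, and 0.295 with an estimated correlation). The 31 proteasome subunits had a median of 0.37, with 30 higher (13 rose when adjusted over the list alone; adjusted p = 4.46e-10, and 0.295 with an estimated correlation). The 16 fast-fibre sarcomere genes were all lower with a median of -0.67 (adjusted p = 8.09e-07, and 0.295 with an estimated correlation). Glycolysis and glycogen had a median of -0.46 (adjusted p = 7.19e-05) and the TCA cycle and fatty-acid oxidation of -0.25 (adjusted p = 0.000134), against 0.347 and 0.425 with an estimated correlation. The 14 endothelial markers, all lower, had a median of -0.47 (3 fell when adjusted over the list alone; adjusted p = 3.41e-07, and 0.274 with an estimated correlation). Smooth muscle and pericytes had -0.32 (adjusted p = 0.0188) and extracellular matrix and fibrosis -0.30 (adjusted p = 0.00157), against 0.295 and 0.413 with an estimated correlation. The myogenic list had a median of 1.24 (6 rose when adjusted over the list alone; adjusted p = 0.00157) and the immediate-early list of 0.55 (2 rose when adjusted over the list alone; adjusted p = 0.00157), each at 0.295 with an estimated correlation. The polyamine and p53-target list had 0.26 (5 rose when adjusted over the list alone; adjusted p = 0.0078, and 0.18 with an estimated correlation). Autophagy and lysosome had 0.19 (adjusted p = 0.0253), antioxidant and metal response 0.13 (6 rose when adjusted over the list alone; adjusted p = 0.0386) and the unfolded protein list 0.28 (adjusted p = 0.0386), each at 0.295 with an estimated correlation. The macrophage markers had a median of -0.0078 while their mean was 0.21 and the test pointed up, and the list did not pass (1 rose when adjusted over the list alone; adjusted p = 0.584). In the lists of this paragraph with no such count given, 0 genes passed when adjusted over the list alone.

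The triceps contrast called 18 probe sets with limma, all higher, and 1145 at an unadjusted p under 0.05. Groups did not overlap for 526 probe sets (6.99%), where chance gives 2.86%. The count was 36 without NTg replicate 1, 8 without NTg replicate 2, 3 without NTg replicate 3, 11 without SOD1 replicate 2 and 3 without SOD1 replicate 4. The calls of Sln and Nabp1 held whichever array was left out while Sh3d19 lost its call in each case. The count was 167 without crush replicate 4, 146 higher and 21 lower. That array enters only through the shared estimate of spread, and the alternative was chosen after seeing the data. The antioxidant list lost its call without NTg 1 or 4 or SOD1 1 or 3 (adjusted p up to 0.166) and the autophagy list without NTg 4 or SOD1 3 (0.0834). The matrix (median -0.14, adjusted p = 0.25) and immediate-early lists (median 0.23, adjusted p = 0.108) lost theirs without SOD1 1, and smooth muscle without NTg 1 or SOD1 1 (0.107). The unfolded protein list lost its call without NTg 2, 3 or 4 or SOD1 2 or 3 (0.132). Without SOD1 4 the medians of glycolysis, autophagy and unfolded protein genes were -0.30, 0.11 and 0.16 and that of the antioxidant list was 0.20. The antioxidant median was 0.052 and 0.084 without SOD1 1 and 3, and 0.21 without NTg 2. That of the unfolded protein list was 0.18 without NTg 3.

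Whether the SOD1 effect itself differed between the muscles was tested as an interaction. Several lists passed as lists although no probe set did. The 31 matrix genes had a median log2 difference, gastrocnemius minus triceps, of 0.53 (adjusted p = 1.78e-09, and 0.5 with an estimated correlation). Above 0 were also the macrophage markers (0.82, adjusted p = 4.41e-07), the complement and antigen presentation genes (0.75, adjusted p = 0.000125), the endothelium (0.43, adjusted p = 0.00186), fibroblast and fibro-adipogenic cells (0.50, adjusted p = 0.00365) and the interferon response (0.66, adjusted p = 0.0173), each at 0.5 with an estimated correlation. The fast-fibre genes (0.81, adjusted p = 0.000125), the respiratory chain (0.22, adjusted p = 0.000125) and the adipocytes (0.93, adjusted p = 0.0201) lay above 0 too, at 0.585, 0.719 and 0.648 with an estimated correlation. Glycolysis and glycogen lay below 0 (-0.16, adjusted p = 0.04, and 0.719 with an estimated correlation). Adjusted over the list alone, 3 complement, 2 macrophage and 1 endothelial gene passed, all upward, and 0 in the other lists of these 10. Limma called 0 probe sets, with 710 at an unadjusted p under 0.05 and a smallest adjusted p of 0.386. Without NTg triceps replicate 1, 34 passed, and 1 passed without SOD1 gastrocnemius replicate 1. The adipocyte call was lost without NTg gastrocnemius 4, NTg triceps 4 (median 0.26), or SOD1 triceps 2 or 4 (adjusted p up to 0.429), and its median was 1.46 without SOD1 triceps 3. The interferon call was lost without NTg triceps 4 (median 0.41), SOD1 gastrocnemius 2, or SOD1 triceps 1 or 4 (up to 0.0999), and that of the respiratory chain without SOD1 triceps 4 (0.057). Glycolysis lost its call without NTg gastrocnemius 3 or 4, NTg triceps 1 or 4, SOD1 gastrocnemius 4, or SOD1 triceps 1 or 3 (up to 0.568), with medians from -0.24 (without SOD1 gastrocnemius 1) to -0.028 (without SOD1 gastrocnemius 4). The fast-fibre median was 0.52 without SOD1 triceps 2, the endothelial median 0.24 without SOD1 triceps 1 and the respiratory median 0.32 without NTg triceps 4.

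The genes called in triceps were largely among those of gastrocnemius. Of 18 probe sets, 14 were called in gastrocnemius in the same direction, where independent lists would share 1.07, and Galnt7, Nxn, Sh3d19, Sln and Tubb6 were called in crushed muscle as well. Across probe sets, which are not independent replicates, the log2 changes in both muscles correlated with Pearson's r = 0.618 and a covariance of 0.101. The count for independent lists does not allow for muscles of the same mice. With the replicate numbers taken as mice, shared mice and no change would give a covariance of 0.0104, and 0.0135 under the pairing that gives most, a reference added after seeing the data. The shared count was 9 without NTg gastrocnemius replicate 1 or 4, 8 without SOD1 gastrocnemius 3 or 4, 7 without NTg triceps 2, and 2 without NTg triceps 3 or SOD1 triceps 4.

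The nerve crush served as a control for denervation, and the comparison asked what changed in gastrocnemius 2 weeks after it. Sln rose 18.5-fold (log2 change 4.21, SE 0.61, adjusted p = 0.00117) and Tubb6 8.77-fold, from a dim NTg mean of 3.14. Without NTg replicate 2 the fold of Sln was 12.2, and without crush replicate 4 that of Tubb6 was 5.45. Cbr2, a carbonyl reductase, rose 5-fold (log2 change 2.32, SE 0.33, adjusted p = 0.00108), Sh3d19 3.99-fold, Serpinb6a, a serine protease inhibitor, 3.44-fold, Mid1ip1 3.31-fold, Rhoc 2.41-fold, Gpx1, the glutathione peroxidase, 2.35-fold, Map1lc3a 2.26-fold and Myf6, a myogenic regulator, 2.21-fold. Pfkfb3 fell by 3.13 (SE 0.54, adjusted p = 0.00403). Mbp, the myelin basic protein, fell by 2.35 (SE 0.52, adjusted p = 0.0163), from 8.98 ± 0.22 (SD, n = 4) in NTg to 6.63 ± 1.37 in crushed muscle, a log2 change that was -2.95 without crush replicate 1. Pla2g7 fell by 1.81, Ppp1r1a by 1.73, Ces1d by 1.65, Gpt2 by 1.5, Pim1, a serine/threonine kinase, by 1.48, Tuba8 by 1.45, Rasd2 by 1.41 and Ccnk by 1.37.

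**Figure D4:**
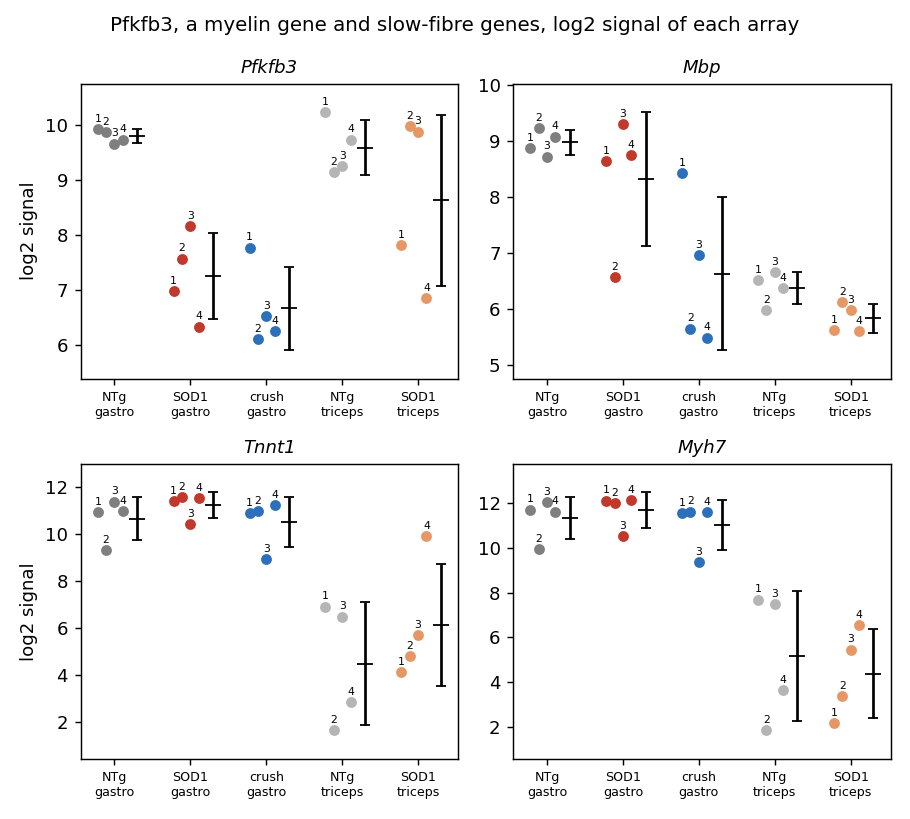
Log2 signal (y axis) of Pfkfb3, Mbp and the slow-fibre genes Tnnt1 and Myh7 for each array of the 5 groups (x axis); points are arrays labelled with their replicate number, and bars are the group mean ± SD of 4 arrays. Pfkfb3 had means of 9.79 in NTg, 7.25 in SOD1 and 6.66 in crushed gastrocnemius.

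Only the myogenic list passed as a list after crush, with a median log2 change of 0.80. Myf6 and Vim rose among its 11 genes (3 when adjusted over the list alone; adjusted p = 0.0288), and with an estimated correlation the adjusted p was 0.424. Leaving out crush replicate 4 ended that call (median 0.50, adjusted p = 0.0649), and 6 other lists then passed, all higher after crush. These were the TCA cycle and fatty-acid oxidation (median 0.30, adjusted p = 3.88e-08), the respiratory chain (0.18, adjusted p = 9.19e-05), and macrophages (0.37), complement and antigen presentation (0.61), matrix (0.28) and cell cycle (0.31) at an adjusted p of 0.048 each, with 0.458, 0.635, 0.57, 0.556, 0.635 and 0.458 with an estimated correlation. In this replicate Chrna1 was at 11.34 and in the other 3 at 6.97 to 7.40, and Myog was at 10.14 against 6.31 to 7.09. Chrna1 had a log2 change of 1.79 (adjusted p = 0.178) in the whole group. Without this replicate the log2 changes of Myf6, Sh3d19 and Rhoc went from 1.14, 1.99 and 1.27 to 0.65, 1.32 and 0.81, and Rhoc lost its call (adjusted p = 0.0775). Among list members, the antioxidant genes Gpx1, Txn2 and Prdx2 rose (3 when adjusted over the list alone), another probe set of Prdx2 having a log2 change of -0.098. Ccnd1, the cyclin D1 gene, rose 2.09-fold (2 rose in the cell cycle list when adjusted over the list alone). Fbxo32, the atrophy ubiquitin ligase atrogin, fell by 0.79 (1 when adjusted over the list alone). The autophagy genes Ulk1 and Tfeb fell by 0.62 and 0.68 while Map1lc3a rose (2 and 2 when adjusted over the list alone). Ppp1r3c, a glycogen targeting subunit of protein phosphatase, fell by 1.05, and with Pfkfb3 made 2 falls among 24 glycolysis and glycogen genes (2 fell and 1 rose when adjusted over the list alone; list adjusted p = 0.0599). Phlda3 rose 1.53-fold and Smox fell by 1.34 (1 and 2 when adjusted over the list alone). Hoxa10, Ighm and Dnajc3 fell by 0.85, 1.06 and 0.62 (1 each when adjusted over the list alone), another probe set of Dnajc3 having a log2 change of 0.11. Of 3 Schwann cell and nerve markers, Mbp fell (2 fell when adjusted over the list alone; list adjusted p = 0.0599). The 11 macrophage markers had a median of 0.36 with 0 called over all probe sets and adjusted over the list alone (adjusted p = 0.0599).

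Limma called 311 probe sets after crush, 81 higher and 230 lower, in 244 genes, with 1554 at an unadjusted p under 0.05. Groups did not overlap for 1232 (16.4%), where chance gives 2.86%. The count was 159, 120, 126 and 94 without NTg replicates 1 to 4, and 193 and 109 without crush replicates 1 and 2. Without crush replicate 4 it was 395 (171 higher and 224 lower), and 218 of these were among the 311. The excess of falls over rises was thus far smaller without that array. Of 33 called genes named by rule or list, 14 kept their call whichever array of the compared groups was left out, Sln, Pfkfb3, Cbr2 and Gpx1 among them, while Mbp lost its call without NTg 2 or 4 or crush 2 (adjusted p up to 0.0606).

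The changes of SOD1 and crushed gastrocnemius against the same 4 NTg arrays were set side by side. In both comparisons Sln, Tubb6, Sh3d19, Gpx1 and Map1lc3a rose and Pfkfb3, Pla2g7, Gpt2, Rasd2, Smox and Tfeb fell. They shared 43 rising and 151 falling probe sets and 0 in opposite directions, where independent lists would share 4.83 and 13.9, numbers that leave out the shared NTg arrays. Across probe sets, which are not independent replicates, the log2 changes correlated with r = 0.769, where simulated unchanged groups sharing the controls gave 0.501 (0.463 to 0.53 in 100 simulations). The covariance was 0.128 against a simulated 0.0249, a difference of 0.103. The simulated noise was independent between probe sets. Deviations of real arrays were not: those of SOD1 replicate 4 and crush replicate 4 correlated with r = 0.447. The simulated ranges are therefore too narrow to give the spread of these values in unchanged groups. With the controls split between the comparisons in 6 ways, r was 0.622 to 0.661, the covariance 0.113 to 0.118, and 1 to 2 rising and 1 to 7 falling probe sets were shared. The shared count of 194 was 80, 60, 74 and 49 without NTg replicates 1 to 4, 97, 108 and 77 without SOD1 replicates 2, 3 and 4, and 123 and 77 without crush replicates 1 and 2. Without crush replicate 4, which stood apart from the other crush arrays, the shared count was 161. The correlation and covariance above include that array and were not computed without it.

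What separated SOD1 from crushed gastrocnemius was tested directly. Macrophage markers were higher in SOD1 muscle, with a median log2 difference of 0.54 and 11 of 11 higher (3 when adjusted over the list alone; adjusted p = 4.44e-05, and 0.491 with an estimated correlation). The interferon response (0.81, adjusted p = 0.00369), complement and antigen presentation (0.56, adjusted p = 0.00731) and matrix genes (0.16, adjusted p = 0.0155) were higher too, at 0.491, 0.491 and 0.604 with an estimated correlation. So were proteasome subunits (0.20, adjusted p = 0.000296), unfolded protein genes (0.26, adjusted p = 0.00645), immediate-early genes (0.32, adjusted p = 0.0145) and the myogenic list (1.32, adjusted p = 0.027), at 0.559, 0.491, 0.491 and 0.491 with an estimated correlation. The respiratory chain (-0.20, adjusted p = 1.34e-05), glycolysis and glycogen (-0.36, adjusted p = 4.71e-05) and the TCA cycle and fatty-acid oxidation (-0.15, adjusted p = 0.00645) were lower, at 0.559, 0.491 and 0.617 with an estimated correlation. Adjusted over the list alone, 5 myogenic, 3 unfolded protein and 1 each of the interferon, complement and immediate-early genes were higher, 1 glycolysis gene was lower, and 0 passed in the other lists of these 11 apart from the macrophages. Limma called 0 probe sets, with 940 at an unadjusted p under 0.05 and a smallest adjusted p of 0.117, and mouse Sod1 had a log2 difference of 0.50 (adjusted p = 0.293).

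That count depended on crush replicate 4, without which limma called 604 probe sets, 281 higher and 323 lower in SOD1 muscle, and without SOD1 replicate 1 it called 2. The genes of the fit without crush replicate 4 were named after their values were seen. Against crush replicates 1 to 3, Cdkn1a was 8.68-fold higher in SOD1 muscle (log2 difference 3.12, SE 0.45, adjusted p = 0.000896), Cpne2 8.67-fold, Tubb6 7.65-fold, Gadd45a 7.57-fold, Chrna1 6.83-fold, Myog 5.91-fold, Atp13a3 5.51-fold, Myod1, a myogenic regulator, 5.03-fold and Lgals3 3.83-fold. Grb14, an adaptor of the insulin receptor, was lower by a log2 difference of -1.85 (SE 0.23, adjusted p = 0.000312), Il15 of -1.41, Gamt, which makes creatine, of -1.36 and Phka1 of -1.39. Crush replicate 4 itself lay on the SOD1 side for these genes. Cdkn1a was at 11.21 and Gadd45a at 10.9 in it, above the SOD1 means of 10.44 and 9.59. Of the rises only Tubb6 (8.33) lay under its SOD1 mean (8.52). Grb14 (3.99) and Gamt (5.85) lay below the SOD1 means of 5.98 and 6.36. The differences thus hold against crush replicates 1 to 3 alone. Of 38 genes of the TCA cycle and fatty-acid oxidation 14 were lower (median -0.40, adjusted p = 8.85e-12, and 0.155 with an estimated correlation), among them Dlat, Dlst, Idh3a and Hadh. Of 55 respiratory chain genes 13 were lower (median -0.35, adjusted p = 2.15e-12, and 0.391 with an estimated correlation), and the proteasome median was 0.35. Lists that passed without crush replicate 4 and not with all arrays were endothelium (median -0.42, adjusted p = 0.00317), cytosolic ribosomal proteins (0.17, adjusted p = 0.00645), autophagy and lysosome (0.19, adjusted p = 0.00873), polyamine and p53 targets (0.27, adjusted p = 0.017) and the neuromuscular junction (0.20, adjusted p = 0.0412), at 0.157, 0.438, 0.155, 0.155 and 0.387 with an estimated correlation.

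The list calls between SOD1 and crushed muscle with all arrays depended on single arrays. The calls of complement, interferon and matrix genes were lost without crush replicate 4 (adjusted p = 0.11, 0.0648 and 0.621), the last without SOD1 replicate 3 too. Immediate-early genes lost theirs without SOD1 1 (median 0.17, adjusted p = 0.248), and had a median of 0.20 without crush 1. The TCA list lost its call without SOD1 4 or crush 1, 2 or 3 (medians of -0.077 to -0.048, adjusted p up to 0.239) and the myogenic list without SOD1 3 or crush 1, 2 or 3 (up to 0.126), with a median of 0.84 without crush 3. Matrix genes had medians of 0.25 and 0.10 without SOD1 1 and 2, 0.30 without crush 1 and -0.033, on the other side of 0, without crush 4. The respiratory median was -0.096 without SOD1 4 and -0.094 without crush 2. The glycolysis median was -0.21 without SOD1 4 and -0.24 and -0.23 without crush 1 and 2, and the proteasome median 0.12 without crush 2 or 3.

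The muscles of NTg mice were compared to give the baseline. Slow-fibre genes were far higher in gastrocnemius: Tnnt1, the slow skeletal troponin T, by 72.7-fold (log2 difference 6.18, SE 1.10, adjusted p = 0.00626), Myh7, the slow myosin heavy chain, by 71.6-fold, Tnni1 by 49.3-fold and Tnnc1 by 31.7-fold. Sln, which is not in the slow-fibre list, was higher by 39.2-fold. These folds are uncertain, since the triceps means were 4.47, 5.17, 4.40, 6.34 and 2.21 on a scale with no floor. They were 37.8 to 128 for Tnnt1 and 33.2 to 128 for Myh7 without triceps replicates 2 and 1, 24.6 and 78.7 for Tnni1 without triceps 4 and 1, 20.9 for Tnnc1 without triceps 4 and 59.5 for Sln without gastrocnemius 2. Of 14 slow-fibre sarcomere genes 12 were higher (13 when adjusted over the list alone), with a median log2 difference of 4.28 (adjusted p = 7.15e-34; adjusted p = 0.0233 with an estimated correlation). Triceps values of Tnnt1 ran from 1.64 to 6.91 between NTg arrays. The Schwann cell and nerve list was higher in gastrocnemius, by a median of 1.06 (1 of 3, 2 when adjusted over the list alone), with adjusted p = 0.000969, and 0.0418 with an estimated correlation. The TCA list was higher by 0.14 (0 when adjusted over the list alone), with adjusted p = 0.0152, and 0.96 with an estimated correlation. Lower in gastrocnemius were Tnfaip2 (log2 difference -1.49), Dpt, the matrix protein dermatopontin (-0.90), Hsph1 (-0.75), C1qb (-0.73) and Lrpap1 (-0.72). The macrophage markers (-0.42, adjusted p = 0.00182), complement and antigen presentation (-0.48, adjusted p = 0.0132), fibroblast and fibro-adipogenic cells (-0.24, adjusted p = 0.0272) and adipocytes (-0.66, adjusted p = 0.0472) were lower. Adjusted over the list alone, 3, 2, 3 and 0 of their genes fell, and with an estimated correlation their adjusted p was 0.617, 0.617, 0.617 and 0.96.

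Limma called 129 probe sets between the muscles, 114 higher and 15 lower in gastrocnemius, in 108 genes, with 1077 at an unadjusted p under 0.05. Groups did not overlap for 772 (10.3%), where chance gives 2.86%. The description of NTg triceps replicate 4 names gastrocnemius while its title, source and tissue name triceps. Its Hoxd10 signal was 0.89, where the other triceps arrays lay from 0.0066 to 1.80 and the gastrocnemius arrays from 2.42 to 5.35. All these values lie under the level of the filter for dim probe sets, on a scale with no floor. Hoxd10 therefore cannot settle which label is right. Above the filter, Hoxa10 (hindlimb) had a log2 difference between the NTg muscles of -0.035. Hoxd8 (forelimb) was higher in gastrocnemius by 0.39. Neither position list passed (camera, adjusted p = 0.999 and 0.269). The count was 37, 81, 33 and 43 without NTg gastrocnemius replicates 1 to 4, and 327, 30, 48 and 31 without NTg triceps replicates 1 to 4. Tnni1 lost its call without gastrocnemius 3 or triceps 2 or 4 (adjusted p up to 0.0604), and all named falls but Lrpap1 lost theirs in 5 to 7 of 8 cases (up to 0.193). Without triceps 4 the calls of the TCA, adipocyte, complement, fibroblast and macrophage lists were lost (up to 0.985), the macrophage median being -0.26 and the adipocyte median -0.15. So were those of TCA without gastrocnemius 3 (median 0.087, and 0.09 without triceps 2), adipocytes without gastrocnemius 1 or 4 or triceps 1, and fibroblasts without gastrocnemius 3 or 4 or triceps 2.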

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

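The tests of cells of another type, of a batch shared by replicate number, of a pairing by chance and of a larger spread in triceps were chosen only after the result was seen. Fixed beforehand were the tests of a SOD1 array under a crush label, of array scaling and of other splits of the arrays.

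The SOD1 effect in gastrocnemius minus that in triceps was tested for each gene list. The following 10 gene lists are given because they passed camera in that test with the preset inter-gene correlation. No member of these lists was called over all probe sets (limma called 0 probe sets, with 710 at an unadjusted p under 0.05), and the brackets count the members whose difference, gastrocnemius minus triceps, lay above 0. The adjusted p was 1.78e-09 for extracellular matrix and fibrosis (31 of 31), 4.41e-07 for macrophages (11 of 11) and 0.000125 each for complement and antigen presentation (6 of 6), fast-fibre sarcomere (14 of 16) and the respiratory chain (52 of 55). It was 0.00186 for endothelium (13 of 14), 0.00365 for fibroblast and fibro-adipogenic cells (8 of 10), 0.0173 for the interferon response (5 of 5), 0.0201 for adipocytes (9 of 9) and 0.04 for glycolysis and glycogen (9 of 24). With an estimated correlation 0 of the 10 passed.

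Single arrays lay far from the other 3 of their group, by Dixon's criterion at 95%, in 29 of 433 groups of values of named genes (6.7%), where chance gives about 1 in 20. Crush replicate 4 held 8 of the 29. In it Chrna1 was at 11.34 (nearest other crush array 7.40), Myf6 at 11.18 (9.39), Lgals3 at 8.68 (6.46), Rhoc at 9.30 (7.59) and Phlda3 at 10.47 (9.91), while Dlat at 8.19 (9.49), Pdk2 at 8.93 (10.06) and Tuba8 at 7.64 (8.71) lay below. In the other crush arrays, Retn was at 7.60 (6.23) in replicate 1 and Rasd2 at 7.38 (6.90) in replicate 3.

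Among NTg gastrocnemius arrays, replicate 1 had Bhlhe40 at 8.13 (nearest other array 8.94), Cldn5 at 7.11 (6.13), Fbxo32 at 8.31 (8.72) and Rps19 at 10.01 (9.81). Replicate 2 had Tnnc1 at 10.14 (11.69), replicate 3 had Mt1 at 7.78 (7.23), and replicate 4 had B2m at 9.69 (10.02), C1qa at 2.88 (5.86) and Rasd2 at 8.88 (8.33). NTg triceps replicate 4 had Tagln at 6.76 (6.10). Among SOD1 gastrocnemius arrays, replicate 3 had Slc25a20 at 8.98 (9.44), and replicate 4 had Hspa4 at 8.37 (7.90) and Robo4 at 5.21 (5.81). Among SOD1 triceps arrays, H2-Aa was at 8.32 (9.50) in replicate 1, Tpm1 at 7.64 (11.15) in replicate 2, and Kcnj8 at 6.09 (5.54) and Lipe at 8.02 (5.87) in replicate 3. In SOD1 triceps replicate 4 Ankrd1 was at 10.80 (6.73) and Chac1 at 6.01 (8.91).

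Crush replicate 4 stood apart from the other 3 crush arrays, by 1.80 on the log2 scale in the mean of the myogenic list. Array scaling as the whole cause is argued against, since 99.4% of that gap stayed after quantile normalization. More cells of the 6 types with a list compared here are argued against too. The highest gap over these lists (macrophages at 0.033, others at -0.84 to -0.38) was 1.84% of that of the myogenic list. Muscle precursor cells had no list of their own, and the lists for lymphocytes and blood cells had too few tested genes. For these cells the test decides nothing. A SOD1 gastrocnemius array carrying a crush label cannot be told apart from a crush array that differs. A median position was taken over 114 probe sets that part crush replicates 1 to 3 from both SOD1 and NTg gastrocnemius. On this scale 0 is the SOD1 mean and 1 the mean of these crush arrays. Replicate 4 had a median position of -0.333, and SOD1 triceps arrays lay from -0.368 to -0.214. Crush replicates 1 to 3, held out in turn, lay at 0.711, 1.03 and 0.962. Those 3 positions rest on other probe sets, selected anew without the array held out (45, 13 and 30). Replicate 4 lay below the SOD1 gastrocnemius arrays (-0.166 to 0.135), which themselves set the 0 point. NTg gastrocnemius (-0.0581 to 0.111) and triceps (-0.0541 to 0.033) lay near 0 as well. The position therefore shows an array unlike crush replicates 1 to 3, and it cannot tell whether the array is like or unlike SOD1. On principal component 1 crush replicate 4 (38.3) lay nearest SOD1 gastrocnemius replicate 4 (36.0). SOD1 gastrocnemius replicate 1 (9.15) lay nearest the other crush arrays (up to 5.51). An exchange of labels between crush replicate 4 and SOD1 replicate 1 was not tested beyond the splits below. No biological explanation was tested.

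SOD1 replicates 1 and 4 deviated from their group means alike in gastrocnemius and triceps (r across probe sets 0.572 and 0.622, against -0.101 and -0.0366 for replicates 2 and 3). A batch shared by arrays of the same number cannot be told apart from other causes. Against it, the excess of NTg replicate 4 in the mean of the myogenic list was -24% of that of SOD1 replicate 4 in gastrocnemius (itself 0.18) and -21.9% in triceps (1.18), while for it, SOD1 replicates 1 and 4 correlated above 0 with the same number in NTg triceps or crush in 8 of 12 pairs with the groups of other mice (-0.249 to 0.482), the negative ones all with NTg gastrocnemius. Pairing by chance stays open, with an exact one-sided permutation p of 0.0833 (2 of 24 pairings as high; mean r 0.264, highest other 0.355). A difference between mice that reached both muscles may be an explanation, but no label ties these numbers to mice and it was not tested.

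Fewer probe sets passed in triceps (18) than in gastrocnemius (902) for SOD1 against NTg. The median SD between arrays was 0.222 and 0.254 in NTg and SOD1 triceps, against 0.155 and 0.206 in gastrocnemius. The fit gave all groups 1 shared spread, with a median SE of 0.174 in both comparisons. A larger spread in triceps could therefore not widen the triceps SE alone. The size of the effects was taken as root mean square log2 after taking off the sampling variance from that shared spread. It was 0.283 in triceps (0.208 to 0.328 on leaving out each array) and 0.413 in gastrocnemius (0.353 to 0.48). These values argue against a larger spread in triceps as the cause of the lower count. A smaller response of the fore limb muscle at this age may be an explanation and stays a hypothesis. The difference itself was tested per probe set, where limma called 0 with 710 at an unadjusted p under 0.05.

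For the count of SOD1 against NTg gastrocnemius, other splits of the same arrays argue against chance (902, highest other split 0, 1 of 35 splits as large). The same holds for crush against NTg (311, highest other 2, 1 of 35). The least these splits can give is 1 of 35, and no adjustment was made over the comparisons. Between the muscles of NTg mice (129, highest other 26, 1 of 35) the splits cannot exclude chance. The design text gives the same NTg mice for both muscles, so those arrays cannot be exchanged freely. Chance was not excluded for SOD1 against NTg triceps (18, highest other 30, 2 of 35). The splits decide nothing for SOD1 against crush (highest other 1356, 35 of 35) and the difference between muscles (highest other 994, 100 of 100), since limma called 0 in both, with 940 and 710 at an unadjusted p under 0.05, and every split is as large as 0. Splits that call so many probe sets point to a structure of the samples. The split with 1356 set crush replicate 4 beside SOD1 replicates 2 to 4, and SOD1 replicate 1 beside crush replicates 1 to 3. The split with 994 kept the gastrocnemius groups as labelled and mixed the triceps groups, so that the SOD1 effect in gastrocnemius remained in the difference. For the number of gene lists called, chance was excluded in none of the 6 comparisons. The number was 9 for SOD1 against NTg gastrocnemius (highest other 11, 11 of 35 splits as large), 14 in triceps (15, 2 of 35), 1 after crush (17, 35 of 35), 11 for SOD1 against crush (15, 9 of 35), 10 for the difference between muscles (15, 13 of 100) and 7 between the NTg muscles (12, 15 of 35).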

How the results depend on the processing

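The fits without crush replicate 4 or NTg triceps replicate 4, in comparisons that do not hold them, were chosen only after the result was seen. Over all alternatives, counts stayed within 1.5 times in 124 cases, were higher in 17 and lower in 56. The 124 include counts of gene lists and the many fits in which SOD1 against crush or the difference between muscles stayed at 0. They therefore overstate how stable the counts with calls were. Values of named genes kept direction and side of the threshold in 4317, lost their call in 452, gained one in 109, changed sign uncalled in 16 and reversed in 4. Called lists kept theirs in 588 cases and lost it in 116. Limma with array weights, where crush replicate 4 had a weight of 0.193, called 2512 probe sets for SOD1 against NTg gastrocnemius (902 without weights), 50 in triceps (18), 1245 after crush (311), 1282 for SOD1 against crush (0, with 940 at an unadjusted p under 0.05), 18 for the difference between muscles (0, with 710) and 360 between NTg muscles (129). The cause was not tested for any change here unless named. An added 2-fold threshold, stricter by construction, left 243 in SOD1 gastrocnemius, 70 after crush and 65 between NTg muscles. A fit on the compared arrays alone gave 1768 in SOD1 gastrocnemius. In triceps, a filter at 60%, which tests fewer probe sets, gave 7, and the 75th percentile and quantile normalization gave 9 and 9. Between NTg muscles the filter at 60% gave 80, the mean of the probe sets of a gene 40, and the mouse as a random block (consensus correlation 0.248) 361. With the replicate number as a block (replicate block), the counts were 1310, 104, 494, 0, 0 and 193 in the order above and 51 lists passed, but not every sample correlates best with its own number. With an estimated inter-gene correlation 2 of 52 lists passed. Leaving out each array gave 178 to 1341 in SOD1 gastrocnemius, 3 to 167 in triceps, 94 to 395 after crush, 0 to 604 for SOD1 against crush, 0 to 34 for the difference between muscles, 30 to 327 between NTg muscles and 46 to 63 lists. The highest values in the first 4 came without crush replicate 4. Without NTg triceps replicate 4 the counts of SOD1 gastrocnemius, crush and SOD1 against crush were 915, 348 and 0. The overlap of SOD1 and crush, 194 probe sets, was 49 to 232 on leaving out an array. It was 3, 4, 6, 2, 9 and 5 with SOD1 against NTg replicates 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4 and crush against the others, where each comparison had fewer arrays. The overlap of both muscles, 14, was 8 after quantile normalization and 2 to 17 on leaving out an array. Other probe sets reversed the direction of Dnajc3 after crush (0.11), Prdx2 after crush (-0.098), Ppp3cb in SOD1 gastrocnemius (0.27) and Psmd11 in SOD1 gastrocnemius (-0.0013). Alternative pseudocounts were not run, since the values were already on a log2 scale. Signals near background limit the folds of genes with dim NTg values, and no detection calls were used.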

Other observations

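Genes in this part were named after their values were seen, and the fits with no filter for dim probe sets and without crush replicate 4 are used here for them. Several genes of denervated and embryonic muscle lay below the filter. Those named here are examples, with no count of genes below the filter that fell or were not called. The myogenic list had 18 measured members with 11 above the filter, and the neuromuscular junction list 15 with 9 above it. In the fit with no filter, Chrng, the embryonic gamma subunit of the acetylcholine receptor, was 41.6-fold higher in SOD1 than in NTg gastrocnemius (log2 change 5.38, SE 1.38, adjusted p = 0.0222), from a dim NTg mean of 1.52 to 6.90. The transcription factor gene Runx1 was 14.1-fold higher (log2 change 3.82, adjusted p = 0.0158), the embryonic myosin gene Myh3 8.32-fold (adjusted p = 0.02), the cardiac troponin T gene Tnnt2 10.4-fold (adjusted p = 0.0246) and the adhesion molecule gene Ncam1 3.67-fold (adjusted p = 0.0404). Junb was 4.08-fold higher in gastrocnemius (adjusted p = 0.0113) and 5.51-fold in triceps (adjusted p = 0.0182). Of the macrophage list, the members Cd52, Ptprc and Tyrobp, which lay below the filter, were 2.31-, 2.01- and 1.98-fold higher in gastrocnemius (adjusted p = 0.0342, 0.0342 and 0.0262). The list had 17 measured members, 11 of them above the filter, and its remaining members below the filter are not given here. In triceps Runx1 and Myh3 had log2 changes of 3.74 and 3.23 (adjusted p = 0.095 and 0.0867), and Chrng of 2.94 (adjusted p = 0.356). After crush Chrng had a log2 change of 1.61 (adjusted p = 0.592).

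Against NTg, crush replicates 1 to 3 were compared alone. Gamt, which makes creatine, was 3.12-fold higher (log2 change 1.64, SE 0.17, adjusted p = 8.7e-05), the apelin receptor gene Aplnr 3.47-fold (adjusted p = 0.0139), Ccnd1 2.61-fold (adjusted p = 0.000985) and Grb14 2.46-fold (adjusted p = 0.00463). In crush replicate 4, Gamt, Aplnr and Grb14 (5.85, 6.45 and 3.99) lay below the NTg means (6.08, 6.61 and 6.53). Ccnd1 at 6.38 lay just above its NTg mean of 6.27. Wnt4 fell by 1.80 (adjusted p = 0.00742), Pim1 by 1.69 (adjusted p = 0.00114), Klf10 by 1.5 (adjusted p = 0.00186) and Txnip by 1.34 (adjusted p = 0.000546). Rapsn, which anchors the acetylcholine receptor, fell by 0.85 (adjusted p = 0.0102). Of 38 genes of the TCA cycle and fatty-acid oxidation, 9 rose and 0 fell, and of 55 respiratory chain genes 1 rose and 0 fell. Against the same 3 crush arrays, SOD1 muscle had 11 of 31 proteasome subunits higher (adjusted p = 2.77e-10, and 0.157 with an estimated correlation) and 4 of 9 neuromuscular junction genes higher (adjusted p = 0.0412, and 0.387 with an estimated correlation).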
